A study of Mus musculus with 72 samples.

How the data were processed

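RNA from mouse liver and intestine (written INTESTINE (IEC) in the labels) was measured on an Affymetrix mouse gene array after 4 weeks on a ketogenic diet or on chow. There were 72 arrays in 24 groups of 3, 1 group for each combination of 2 tissues, 2 diets and 6 zeitgeber times (ZT, hours after lights on: 0, 4, 8, 12, 16 and 20). Tissue, diet and ZT were read from the labels, where title, source and characteristics gave the same ZT for each array. The labels do not state that the number in a title is an animal, nor that replicates are separate animals, so p values measure the spread between these samples. Numbers shared by a liver and an intestine array did not pair them: across the 22 such pairs the median correlation of residuals was 0.02, against -0.01 for 86 pairs with different numbers. The shared protocol text also mentions 7 days of fructose gavage at 4 g/kg, 30% sucrose in drinking water, and collection at ZT0 and ZT12; whether the gavage or sucrose applies to these samples is not stated, and neither was used as a factor.

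The authors deposited 1 intensity per probe set and array, made with PLIER in Affymetrix Expression Console 1.1.1 according to the processing notes of the labels. Background and normalization settings are not stated there. The intensities are linear, from near 0 to 89033, with array medians of 105 to 119 in liver and 107 to 121 in intestine. The deposited workbook also holds group mean intensity values, each equal within a relative difference of 0.0001 to the mean of the 3 arrays carrying that label, for 25006 of 25006 probe sets in each of the 24 groups. Its other columns, as deposited, are p-values from JTK_CYCLE, BIO_CYCLE and Cyber-T, and, of the unit other, JTK_CYCLE phase lags in hours; the lags were not used here. No counts exist for arrays, so the number of arrays limits the precision.

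Values were taken as log2(intensity + 16); 7.81% of values lay below that pseudocount of 16. Of 35556 probe sets 23162 could be given a gene symbol, from the platform table or, for 1373, from the workbook through RefSeq. For each gene the probe set with the highest mean was kept, and genes below the 40th percentile of mean log2 value were left out, leaving 12463 genes per tissue and 10872 for tests across tissues. Genome positions were not used here.

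Models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The diet effect was the mean of the 6 ketogenic groups minus the mean of the 6 chow groups. Rhythms were tested with a cosinor of 24 h period (a cosine and a sine per diet) and moderated F tests, for each diet and for the difference between diets; amplitude is the height of the fitted peak above the mean on the log2 scale. The same contrasts were compared between tissues. Adjusted p values are Benjamini-Hochberg, with a threshold of 0.05, and "called" means past it. Tests are two-sided unless named otherwise. Gene lists with at least 3 tested members were tested for diet with limma's camera at its preset correlation, and for rhythm differences with a one-sided Fisher's exact test against all tested genes. Fisher's test treats genes as independent, so its p values can be too small where members of a list are correlated. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and statmod 1.5.0, did the rest. A clock time was read for each array from clock and clock output genes called rhythmic on both diets. It was the ZT at which the chow curves, fitted without that array, correlated best with the array. Diets were compared with 100000 permutations of the diet labels within time points.

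The groups, comparisons, gene lists, and the rule for the genes named were fixed before the data were examined. The rule took, per tissue, the 8 largest rises and the 8 largest falls with 1 sign at all 6 time points, 3 members of each called list with the smallest adjusted p, the clock list genes, the 5 largest amplitudes per diet, and the 6 smallest adjusted p values in each direction of the rhythm and tissue tests; predicted genes and RIKEN clones were skipped. A gene that the rule took is not reported here. Alternatives were no filter or a 60th percentile filter, a pseudocount of 1, quantile normalization, median centring, an intensity trend with robust eBayes, each array left out in turn, ZT as an additive factor, a 1.5-fold minimum, each diet fitted alone, tests of any time difference, a diet by time point interaction, rhythmic genes alone, the title number as a block, camera with an estimated correlation, and fry. Added after seeing the data were the clock times, the list tests between tissues, and runs without 3 intestine arrays whose residual SD was over 1.5 times the tissue median, or with 2 liver chow arrays left out or exchanged.

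The tests were tested on simulated data with 66 or 67 genes changed at each size in the same numbers of arrays. Changes of 1.25-fold were recovered for 92.5% of genes in liver, 94.0% in intestine and 92.5% of tissue differences, 1.5-fold changes for 100% in each, and 2-fold changes for 100%, 98.5% and 100%. Rhythms of amplitude 0.2, 0.4 and 0.8 were recovered for 83.6%, 98.5% and 98.5% of genes in liver and 70.1%, 98.5% and 100% in intestine. Rhythm differences of those sizes were recovered for 46.3%, 89.6% and 98.5% in liver, 29.9%, 86.6% and 98.5% in intestine, and 10.4%, 76.1% and 98.5% between tissues. Each rhythm was added to ketogenic arrays alone (of liver alone for the tissue test), with none on chow and the same spread for both diets. These rates therefore do not cover a shift of peak between 2 rhythms, nor the unequal spread of the diets in intestine given below. Of the genes called, 4.41% in liver and 5.34% in intestine for diet, and 8.24% and 2.72% for rhythm difference, had not been changed. A list shifted by 0.4 was recovered in both tissues, but the genes were simulated independently of each other. Members of real lists were correlated (estimated correlation 0.50 for PPARA targets in liver), so this recovery does not carry over to them. For the rhythm list test 4 members of a list were marked as called by hand, so its recovery in both tissues was set in advance.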

Results

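Gene expression was measured in liver and intestine of male C57BL/6J mice kept on a cycle of 12 h light and 12 h dark and fed a ketogenic diet or chow for 4 weeks from 8 weeks of age. Each tissue had 36 arrays, 18 per diet, with 3 arrays at each of 6 time points. The labels name the circadian genes of liver and gut under these diets as the subject. The questions were therefore which genes each diet raised or lowered, which genes followed a 24 h rhythm on each diet, and whether liver and intestine responded alike. In liver no array stood apart from the others, while 3 ketogenic intestine arrays did (ZT0 replicate 1, ZT8 replicate 26 and ZT20 replicate 27).

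In liver 32 of 35 PPARA target genes of fatty acid oxidation rose on the ketogenic diet and 15 of 19 genes of de novo lipogenesis fell (camera adjusted p = 2.7e-24 and 3.3e-13; adjusted p = 0.140 with an estimated correlation for each). Cyp2b9, a cytochrome P450, rose most (probe set 10551218, 31-fold, log2 difference 4.95 ± 0.40 SE, n = 18 per diet), followed by the adipsin gene Cfd (7.04-fold, 2.81 ± 0.22) and Cidec, which encodes a lipid droplet protein (10546929, 6.85-fold, 2.78 ± 0.19). The fatty acid hydroxylase gene Cyp4a14 rose 4.52-fold (2.18 ± 0.27), and Slc16a5, Ifi44, Osbpl3 and Ifit1 rose between 3.02-fold and 3.39-fold. The largest fall was that of Moxd1 (10362186, 17-fold, -4.09 ± 0.52), then those of the trefoil peptide gene Tff3 (10449657, 10.1-fold, -3.34 ± 0.16), Pnpla3 (6.77-fold, -2.76 ± 0.14) and the fatty acid binding protein gene Fabp5 (6.06-fold, -2.60 ± 0.18). Rgs16, the hepcidin gene Hamp2, the stearoyl-CoA desaturase gene Scd1 and Chrna4 fell between 3.78-fold and 4.33-fold. The size of the Cyp2b9 fold rests on low chow values (mean log2 6.07, within-group SD 1.57), and with a pseudocount of 1 the liver diet difference of Cyp2b9 was 5.48 (log2). The rule took these 16 genes only from those with the same sign at all 6 time points, so that agreement was set in advance. The ranks hold among such genes. In all, limma called 6012 of 12463 genes (48.2%), 2397 higher and 3615 lower, with a median fold of 1.11. A change of at least 1.5-fold was reached by 237, 114 higher and 123 lower. With quantile normalization the balance turned: the liver genes higher on the ketogenic diet numbered 2808 and the liver genes lower on the ketogenic diet 2677.

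Of 35 PPARA target genes of fatty acid oxidation tested in liver, 32 rose and 3 were not called (33 rose when adjusted over the list alone). The mitochondrial uncoupling protein gene Ucp2 rose 2.08-fold (1.05 ± 0.06), the thiolase gene Acaa1a 1.60-fold (0.68 ± 0.05) and the acyl-CoA dehydrogenase gene Acadm 1.49-fold (0.58 ± 0.04). This list had a median log2 difference of 0.42 (camera adjusted p = 2.7e-24; adjusted p = 0.140 with an estimated correlation). Of 19 genes of de novo lipogenesis, 15 fell and 4 were not called (15 fell and 1 rose when adjusted over the list alone), with a median of -0.94 (adjusted p = 3.3e-13; adjusted p = 0.140 with an estimated correlation). Among them the fatty acid elongase gene Elovl6 fell 3.05-fold (-1.61 ± 0.07), the pyruvate kinase gene Pklr 3.02-fold (-1.59 ± 0.07) and the acetyl-CoA carboxylase gene Acaca 2.70-fold (-1.43 ± 0.07). Of 24 genes of cholesterol synthesis, 14 rose and 10 were not called (15 rose when adjusted over the list alone), with a median of 0.37 (adjusted p = 6.5e-08; adjusted p = 0.422 with an estimated correlation). The sterol regulator gene Srebf2 rose 1.36-fold (0.45 ± 0.05), the mevalonate kinase gene Mvk 1.70-fold (0.76 ± 0.07) and Cyp51 1.86-fold (0.89 ± 0.10).

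Genes of sugar use fell in liver. Of 21 genes of glycolysis and fructose use, 16 fell, 3 rose and 2 were not called, with the same counts when adjusted over the list alone (median -0.16, adjusted p = 3.7e-05; adjusted p = 0.140 with an estimated correlation). The ketohexokinase gene Khk fell 1.93-fold (-0.95 ± 0.04) and Gpi1, encoding glucose phosphate isomerase, fell 1.55-fold (-0.63 ± 0.03). Of 17 genes of gluconeogenesis and glycogen, 9 fell, 1 rose and 7 were not called (10 fell and 1 rose when adjusted over the list alone; adjusted p = 0.0357; adjusted p = 0.396 with an estimated correlation). Its adjusted p was 0.0501 without chow ZT0 replicate 2 and 0.0507 without ketogenic ZT8 replicate 24. The glycogen phosphorylase gene Pygl fell 1.55-fold and Ugp2, which makes the sugar donor of glycogen, fell 1.41-fold, while Pck1, the cytosolic carboxykinase gene of gluconeogenesis, chosen after its values were seen, rose 1.65-fold (0.73 ± 0.10). Of 12 genes of sugar and peptide absorption tested in liver, 8 fell and 4 were not called (8 fell and 1 rose when adjusted over the list alone; adjusted p = 5.4e-04; adjusted p = 0.140 with an estimated correlation). Khk, already counted above, the aminopeptidase gene Enpep (2.14-fold, -1.10 ± 0.06) and the amino acid transporter gene Slc7a7 (1.57-fold) were among those that fell.

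Interferon response genes rose together in liver, 18 of 19 tested, with 1 not called and the same count when adjusted over the list alone. Ifi44 rose 3.03-fold (1.60 ± 0.10), the antiviral gene Ifit1 3.02-fold (1.60 ± 0.14), the deubiquitinase gene Usp18 2.74-fold (1.46 ± 0.12) and the interferon regulatory factor gene Irf7 (10569102) 2.11-fold (1.07 ± 0.05). The list's median was 0.64 (adjusted p = 1.4e-14; adjusted p = 0.140 with an estimated correlation), and the mean of its genes was above the chow mean of the same time point in 17 of 18 ketogenic arrays. The 16 markers of macrophages, T cells and B cells tested had log2 differences from -0.24 to 0.21, with a median of 0.04. Of 24 genes of drug and xenobiotic metabolism, 16 rose, 4 fell and 4 were not called, with the same counts when adjusted over the list alone (median 0.17, adjusted p = 3.7e-05; adjusted p = 0.140 with an estimated correlation), among them Cyp2c54 (1.45-fold) and the nuclear receptor gene Nr1i3 (1.43-fold).

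Other liver lists were called with members going both ways, and their counts were the same when adjusted over the list alone. Lipid uptake, storage and export had 13 of 31 genes higher and 4 lower (adjusted p = 1.6e-03; adjusted p = 0.399 with an estimated correlation), among them Cd36 (2.37-fold, 1.24 ± 0.12) and Plin4 (1.64-fold, 0.72 ± 0.06). The respiratory chain and TCA cycle had 14 of 32 higher and 5 lower (adjusted p = 8.8e-03; adjusted p = 0.579 with an estimated correlation): Suclg1 rose 1.33-fold, Idh3b rose 1.13-fold, and the citrate synthase gene Cs fell 1.24-fold. Amino acid catabolism and the urea cycle had 8 of 27 higher and 4 lower (adjusted p = 8.6e-03; adjusted p = 0.512 with an estimated correlation), with Agxt 1.55-fold and Tdo2 1.23-fold higher. Without a filter on low values neither of the last 2 lists was called (adjusted p = 0.0801 for the respiratory chain and TCA cycle and 0.142 for amino acid catabolism). Of 6 adipocyte markers tested, which include Cidec, Cfd and Pnpla3, 4 were higher and 1 lower, and the list was not called (adjusted p = 0.0583). In total 11 of 35 lists were called in liver by camera at its preset correlation, 0 with an estimated correlation, where all 11 had an adjusted p of 0.140 or more, and 19 by fry.

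**Figure D1:**
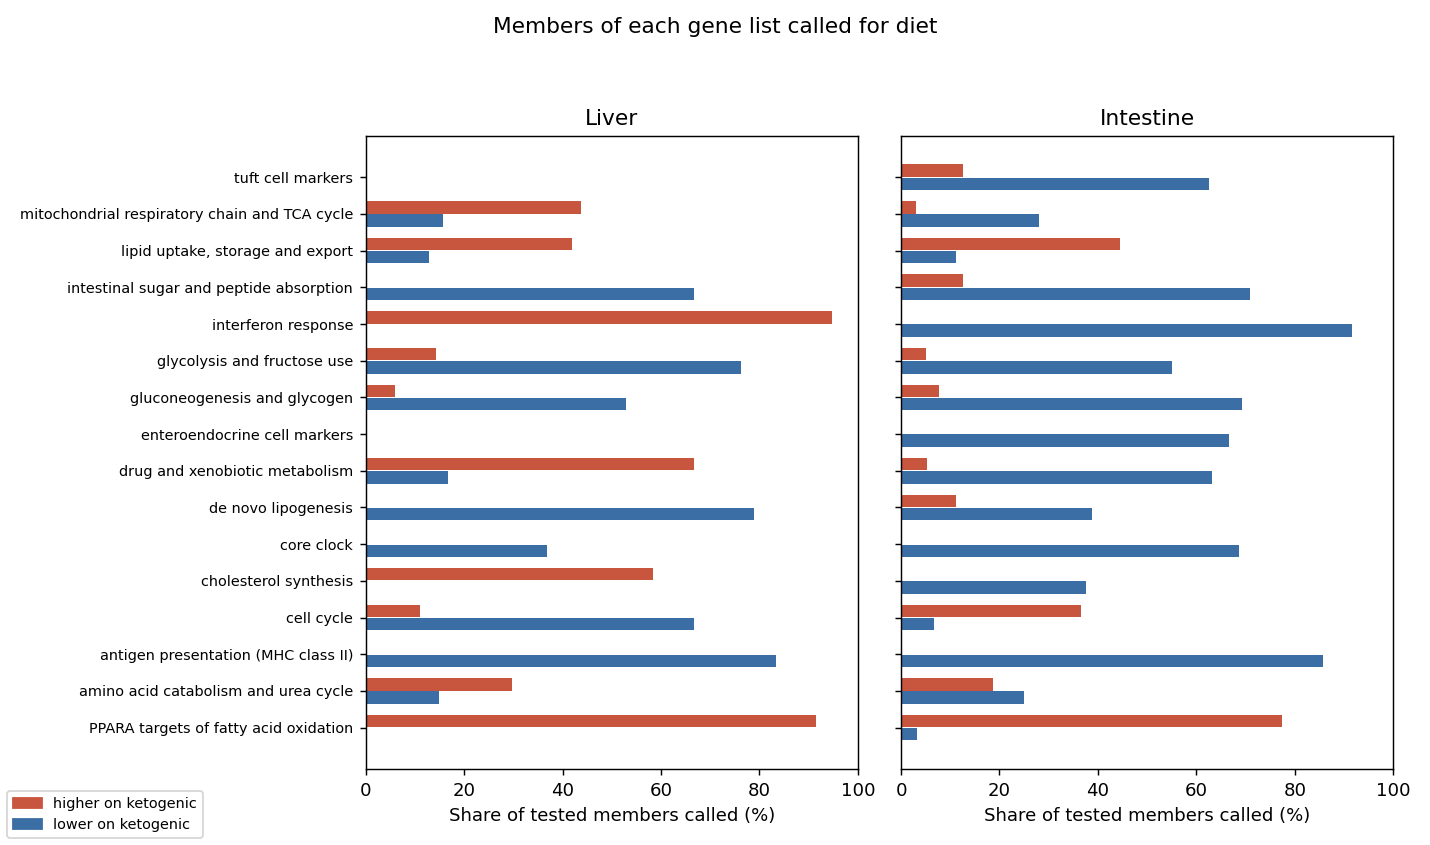
Share of tested members (%, horizontal axis) called higher (red) or lower (blue) on the ketogenic diet for lists called in liver or intestine, and for some of these lists in the tissue where they were not called; an empty place means that no member was called or that the list was not tested. PPARA targets rose in both tissues, while interferon response genes rose in liver (18 of 19) and fell in intestine (11 of 12).

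Rhythms in liver were more numerous on the ketogenic diet, with 4552 of 12463 genes called (36.5%) against 2190 on chow (17.6%) and 1580 on both. The peaks of rhythmic genes lay most often between ZT20 and ZT24 on chow (32.6%) and between ZT4 and ZT8 on the ketogenic diet (33.1%), but these are different sets of genes: the 1580 genes rhythmic on both diets had a median peak shift of 0.20 h (quartiles -0.92 and 1.34 h). The test of the difference between diets called 148 genes, 125 with the larger amplitude on the ketogenic diet and 23 with the larger amplitude on chow, and 108 of the 3582 genes that were called rhythmic on 1 diet only. Tor3a, an interferon-inducible gene, had an amplitude of 0.39 on chow and 1.22 on the ketogenic diet, with peaks at ZT20.6 and ZT20.8 (adjusted p = 1.3e-03). The carboxylesterase gene Ces1d went from 0.12 to 0.40 (adjusted p = 5.4e-03), and Sema4a, Kiz and Gpn3 also had larger amplitudes on the ketogenic diet; Tmie had amplitudes of 0.47 and 0.48 and a peak 3.82 ± 0.60 h later. The lipogenic genes Acly and Elovl6 went the other way, from 0.69 to 0.13 and from 0.47 to 0.06 (adjusted p = 9.1e-03 for each). On chow both peaked early in the dark phase, at ZT14.4 and ZT14.3. Slc25a44 also had the larger amplitude on chow (adjusted p = 2.8e-03), and Cd55, A1cf and Ehbp1 had peaks shifted by 10.6 h, -8.41 h and 9.43 h with amplitudes that differed by less than 2 SE.

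Interferon response genes were over-represented among the 148 liver rhythm differences, with 10 of 19 tested genes called against 1.19% of all genes (Fisher's exact test, adjusted p = 1.2e-13). The test treats genes as independent, while members of this list were correlated (estimated correlation 0.57), so its p value can be too small. Of these 19 genes, 3 were rhythmic on chow and 17 on the ketogenic diet. Macrophage and Kupffer cell markers were rhythmic in 1 of 12 cases on chow and 6 of 12 on the ketogenic diet, and 4 of 12 passed for a rhythm difference at an unadjusted p under 0.01 (adjusted p = 0.0265 for the list). Ifit1 had an amplitude of 0.15 on chow and 1.18 on the ketogenic diet, where it peaked at ZT22.2, and the antiviral gene Rsad2 peaked there at ZT21.9. The mean of the list was 1.01 higher on the ketogenic diet at ZT0, 0.07 higher at ZT12 and 1.44 higher at ZT20, with within-group SDs of 0.11, 0.15 and 0.19. At ZT16 the ketogenic arrays disagreed: they lay at 9.25, 9.76 and 8.62, the last within the chow range of 8.43 to 8.78. Of the lipogenesis genes, 4 of 19 were called, all with larger amplitude on chow (adjusted p = 1.1e-03). No other list of the 35 was called.

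The core clock genes of liver kept their rhythms on both diets: 15 of 19 were called on chow, 16 on the ketogenic diet and 15 on both. Arntl, the activator at the centre of the clock, had amplitudes of 1.39 and 1.62 and peaks at ZT21.0 and ZT20.6, and the repressor gene Nr1d1 2.01 and 2.07 with peaks at ZT5.4 and ZT5.8. The median peak shift of the 15 genes was -0.18 h. limma called a rhythm difference for 0 of the 19 (smallest adjusted p = 0.138), for 0 when adjusted over the list alone and for 2 at an unadjusted p under 0.05. All 19 clock output genes tested were rhythmic on both diets, among them Dbp (1.79 and 2.14), Usp2 (1.63 and 1.82) and Tef (0.68 and 0.80). Of these limma called 0 for a difference (smallest adjusted p = 0.0506), 2 when adjusted over the list alone and 2 at an unadjusted p under 0.05. Those counts depended on the setting. Gys2 was called with a 60th percentile filter (adjusted p = 0.0340), an intensity trend (0.0359) and quantile normalization (0.0452), and Rgs16 with a 60th percentile filter (0.0472). Both were called without chow ZT0 replicate 22 (0.0364 for Gys2 and 0.0355 for Rgs16), chow ZT4 replicate 24 (0.0445 and 0.0388), ketogenic ZT4 replicate 20 (0.0343 and 0.0401) or ketogenic ZT20 replicate 27 (0.0482 and 0.0428). Gys2 was also called without chow ZT4 replicate 4 (0.0276), chow ZT8 replicate 12 (0.0499), chow ZT16 replicate 8 (0.0474), ketogenic ZT8 replicate 7 (0.0359) or ketogenic ZT16 replicate 22 (0.0499).

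The time read from clock genes placed 70 of the 72 arrays within 2.65 h of their labelled time point. The exceptions were both chow livers: ZT8 replicate 12 read 12.5 h, and ZT12 replicate 17 read 8.5 h. Left out, they gave 2233 rhythmic genes on chow, 4627 on the ketogenic diet and a difference for 108 genes, and 5 of 19 interferon genes in place of 10 (adjusted p = 1.6e-05). The peak counts and amplitudes above are from all arrays as labelled. The number of rhythm differences also rested on single arrays: it was 86 without chow ZT4 replicate 6, 93 without ketogenic ZT12 replicate 30, 97 without ketogenic ZT12 replicate 11 or chow ZT16 replicate 7, and 451 without ketogenic ZT4 replicate 20. Ehbp1 and Tmie changed the sign of their small amplitude difference when some arrays were left out.

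**Figure D2:**
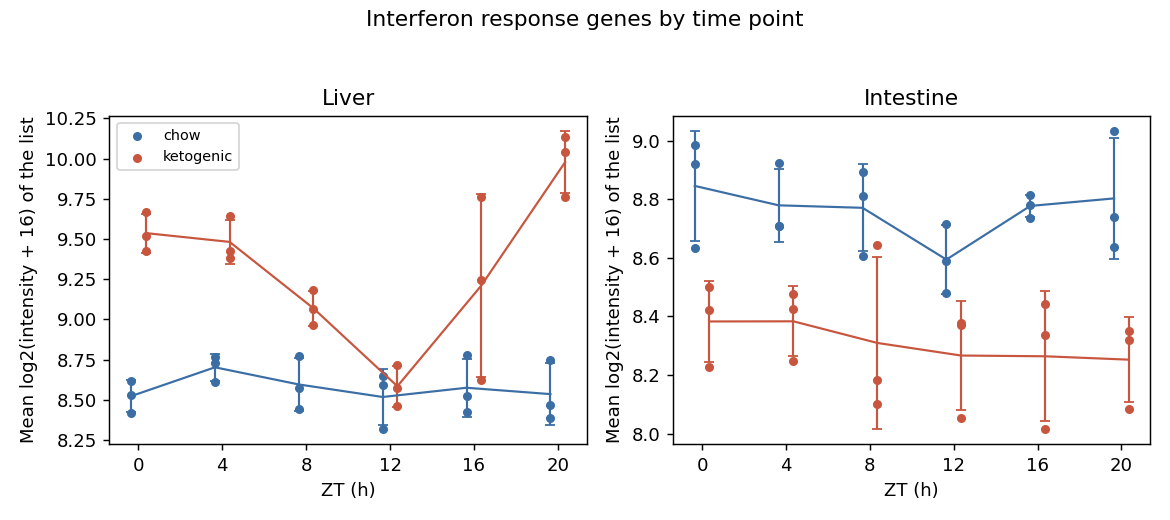
Mean log2(intensity + 16) of the interferon response list (vertical axis, different ranges in the panels) against ZT in hours, with a point for each array and lines and bars for the mean and SD of 3 arrays. In liver the diets differed by 0.07 at ZT12 and by 1.44 at ZT20, and in intestine the ketogenic mean was lower at all 6 time points.

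In intestine 24 of 31 PPARA target genes of fatty acid oxidation rose on the ketogenic diet and 1 fell, and 17 of 24 genes of sugar and peptide absorption fell and 3 rose (camera adjusted p = 4.2e-15 and 5.4e-04; adjusted p = 0.520 and 0.603 with an estimated correlation). The fatty acid hydroxylase gene Cyp4a10 rose 12.3-fold (probe set 10507163, log2 difference 3.62 ± 0.26 SE, n = 18 per diet), and Pdk4, which restrains glucose oxidation, rose 5.05-fold (2.34 ± 0.17). The size of the Cyp4a10 fold rests on low chow values (mean log2 5.46, within-group SD 0.90), and with a pseudocount of 1 the intestine diet difference of Cyp4a10 was 4.39 (log2). Acacb rose 4.71-fold (2.24 ± 0.07), the malic enzyme gene Me1 3.83-fold (1.94 ± 0.10), and Akr1b8, Ptafr and Flvcr2 rose between 2.56-fold and 3.53-fold. The glucose transporter gene Slc2a2 fell most (10491171, 5.18-fold, -2.37 ± 0.15), then Npl (4.91-fold, -2.30 ± 0.13), Cyp2c55 (4.19-fold, -2.07 ± 0.16) and Fgf15, the gut hormone that restrains bile acid synthesis (10559373, 4.17-fold, -2.06 ± 0.23). Defb37, Cyp3a11, the sugar transporter family gene Slc5a4a and the T cell receptor segment Trgv1 fell between 2.43-fold and 3.18-fold. The same sign at all 6 time points was again a condition of the rule for these rises and falls, and their ranks hold among such genes. limma called 6345 of 12463 genes (50.9%), 2454 higher and 3891 lower, with a median fold of 1.12, and 161 with at least 1.5-fold, 59 higher and 102 lower. With quantile normalization the intestine genes higher on the ketogenic diet numbered 3116 and the intestine genes lower on the ketogenic diet 3095.

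Of 31 PPARA targets tested in intestine, 24 rose, 1 fell and 6 were not called (24 rose and 2 fell when adjusted over the list alone). The median was 0.33 (adjusted p = 4.2e-15; adjusted p = 0.520 with an estimated correlation), with Fabp1 1.86-fold higher (0.89 ± 0.08) and Acadl 1.90-fold higher (0.93 ± 0.06). Lipid uptake, storage and export had 12 of 27 genes higher and 3 lower (adjusted p = 4.3e-04; adjusted p = 0.603 with an estimated correlation); the monoglyceride lipase gene Mgll rose 2.41-fold (1.27 ± 0.08) and Slc27a2 1.75-fold. Of 24 genes of sugar and peptide absorption, 17 fell and 3 rose (17 and 4 when adjusted over the list alone; adjusted p = 5.4e-04; adjusted p = 0.603 with an estimated correlation), and the sucrase-isomaltase gene Sis fell 1.31-fold (-0.39 ± 0.03). Of 13 genes of gluconeogenesis and glycogen, 9 fell and 1 rose (adjusted p = 0.0302; adjusted p = 0.602 with an estimated correlation): Ppargc1a fell 1.86-fold and the glycogen branching enzyme gene Gbe1 1.38-fold, while Pck1 rose 2.41-fold (1.27 ± 0.15). Drug and xenobiotic metabolism had 12 of 19 genes lower and 1 higher (adjusted p = 1.3e-03; adjusted p = 0.602 with an estimated correlation), with Ces2a 1.96-fold and Cyp3a25 2.19-fold lower. Cholesterol synthesis had 9 of 24 genes lower and 15 not called (adjusted p = 0.0397; adjusted p = 0.782 with an estimated correlation), among them Tm7sf2 (1.31-fold) and Dhcr7 (1.24-fold); without the 3 arrays standing apart its adjusted p was 0.135, and omission of any of 14 single arrays, such as chow ZT8 replicate 10 (0.0776), took it past 0.05. In the lists of this paragraph with a single count, the count was the same when adjusted over the list alone.

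Interferon and antigen presentation genes fell in intestine. Of 12 interferon genes tested 11 fell and 1 was not called, with the same count when adjusted over the list alone (median -0.34, adjusted p = 2.1e-04; adjusted p = 0.602 with an estimated correlation); Ifit1 fell 2.31-fold (-1.20 ± 0.10) and Rsad2 1.61-fold (-0.68 ± 0.07). Of 7 genes of MHC class II presentation 6 fell (7 when adjusted over the list alone), with a median of -0.94 (adjusted p = 0.0377; adjusted p = 0.603 with an estimated correlation), and H2-Ab1 fell 2.24-fold (-1.16 ± 0.34); the adjusted p was 0.0681 without chow ZT8 replicate 10 and 0.0507 without ketogenic ZT20 replicate 29. In the array of ketogenic ZT0 replicate 1 this list lay at -1.81 relative to the rest of its group (SD of the other arrays 0.96). In the other arrays standing apart it lay at 0.96 (ZT8 replicate 26) and 0.59 (ZT20 replicate 27). T and B lymphocyte markers moved with the interferon and MHC class II genes: 4 of 6 fell and the list was not called (median -0.45, adjusted p = 0.0574). Markers of enteroendocrine cells fell in 8 of 12 cases (9 when adjusted over the list alone; adjusted p = 0.0392; adjusted p = 0.603 with an estimated correlation), among them Chga (1.35-fold), Tph1 (1.38-fold) and Chgb (1.27-fold); omission of any of 7 single arrays took the adjusted p past 0.05, up to 0.0643 without ketogenic ZT0 replicate 2. Tuft cell markers fell in 5 of 8 cases and rose in 1 (6 and 1 when adjusted over the list alone; adjusted p = 8.8e-03; adjusted p = 0.520 with an estimated correlation), with Rgs13 1.66-fold, Dclk1 1.32-fold and Trpm5 1.31-fold lower. With a 60th percentile filter the lists of tuft cells (adjusted p = 0.433), enteroendocrine cells (0.0587) and MHC class II (0.0790) were not called. Cell cycle genes rose in 11 of 30 cases and fell in 2, with the same counts when adjusted over the list alone (adjusted p = 8.5e-04; adjusted p = 0.670 with an estimated correlation), with Mcm2 1.23-fold and Cdk1 1.22-fold higher and Ccne2 1.44-fold lower; fry did not call this list (adjusted p = 0.0882), and in ketogenic ZT0 replicate 1 it lay at -0.95 and Paneth cell markers at -1.32 relative to the rest of its group. In total 12 of 37 lists were called in intestine by camera, 0 with an estimated correlation, where the smallest adjusted p was 0.520, and 25 by fry.

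**Figure D3:**
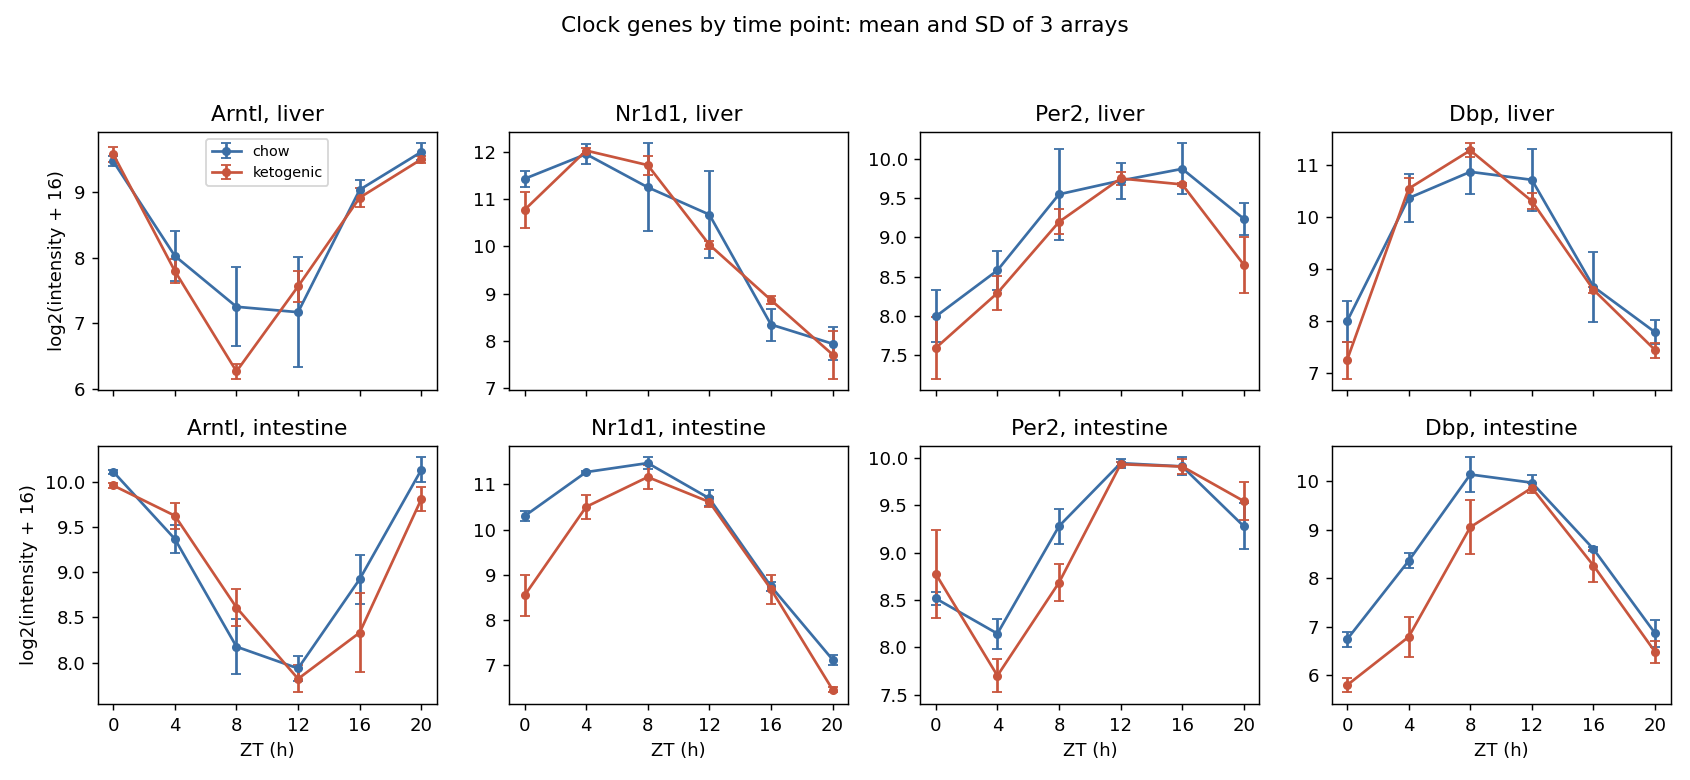
Log2(intensity + 16) of Arntl, Nr1d1, Per2 and Dbp (vertical axes) against ZT in hours in liver (top) and intestine (bottom), as mean and SD of 3 arrays on chow (blue) and on the ketogenic diet (red). In intestine the fitted peak of Arntl came 1.51 h later on the ketogenic diet and that of Dbp 1.26 h later.

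The clock of the intestine ran later on the ketogenic diet. Arntl peaked 1.51 ± 0.33 h later, Nr1d1 1.30 ± 0.44 h, Per2 1.46 ± 0.46 h and Cry1 1.74 ± 0.56 h later, and of the clock output genes Dbp peaked 1.26 ± 0.24 h, Tef 1.05 ± 0.29 h and Nfil3 1.65 ± 0.41 h later. Of the 11 core clock genes rhythmic on both diets, 10 peaked later and 1 earlier, with a median shift of 1.30 h. For single genes limma called a rhythm difference for 0 of 16 core clock genes (smallest adjusted p = 0.107), 8 when adjusted over the list alone and 8 at an unadjusted p under 0.05. For clock output genes it called 0 of 13 (smallest adjusted p = 0.0512), 4 when adjusted over the list alone and 5 at an unadjusted p under 0.05. These counts depended on the setting. Dbp was called with a pseudocount of 1 (adjusted p = 0.0224), quantile normalization (0.0340), median centring (0.0493) and an intensity trend (0.0497). It was also called when any of 12 arrays was left out: chow ZT0 replicate 2 (0.0441), ZT0 replicate 23 (0.0404), ZT4 replicate 25 (0.0390), ZT8 replicate 11 (0.0406), ZT20 replicate 13 (0.0446) or ZT20 replicate 30 (0.0383), or ketogenic ZT0 replicate 1 (0.0231), ZT4 replicate 19 (0.0357), ZT8 replicate 26 (0.0143), ZT16 replicate 6 (0.0182), ZT16 replicate 22 (0.0445) or ZT20 replicate 29 (0.0381). Without the 3 arrays standing apart Dbp, Fbxl21 and Tef were called (adjusted p = 7.9e-03, 0.0142 and 0.0379). The time read from 20 clock genes was 1.29 h earlier on the ketogenic diet (-1.29 ± 0.24 h SE, n = 18 per diet), and earlier on average at all 6 time points. A permutation test gave p = 1e-05, the smallest that the permutations can give. In liver the difference was 0.05 ± 0.41 h (permutation p = 0.914), and 0.16 h without the 2 chow arrays named above (permutation p = 0.553). The shift differed between the tissues by -1.34 ± 0.48 h (permutation p = 2.2e-03). The level of core clock genes also fell in intestine, in 11 of 16 cases with 5 not called and the same count when adjusted over the list alone (median -0.26, adjusted p = 4.3e-04; adjusted p = 0.520 with an estimated correlation), with Nr1d1 1.52-fold and Bhlhe40 1.48-fold lower.

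**Figure D4:**
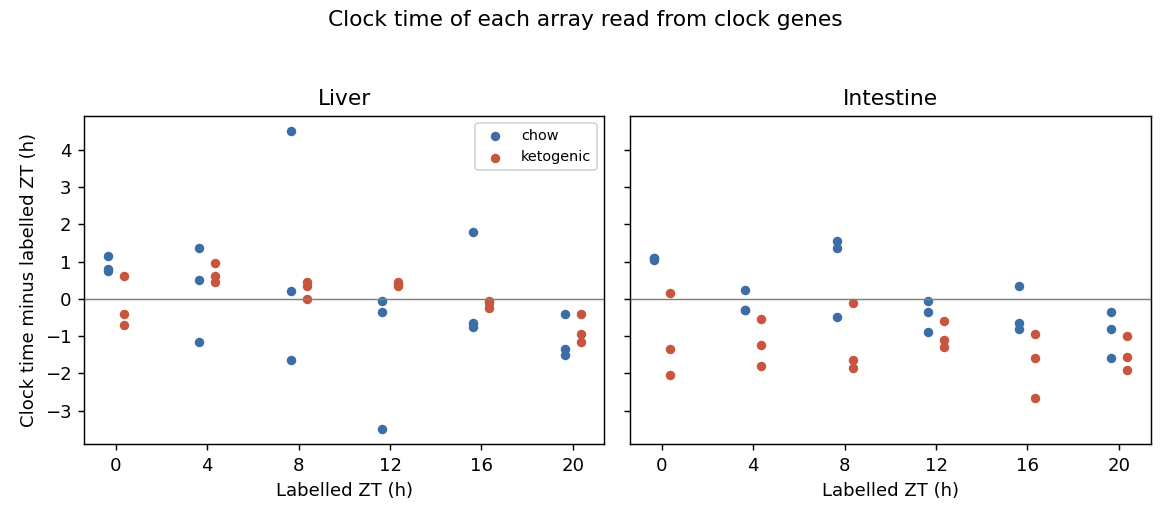
Time read from clock genes minus labelled ZT (hours, vertical axis) against labelled ZT (hours), with a point for each array. The ketogenic intestine arrays lie lower than the chow arrays by 1.29 h on average, and in liver chow ZT8 replicate 12 and ZT12 replicate 17 lie 4.5 h above and 3.5 h below their label.

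Rhythmic genes of intestine numbered 1113 on chow, 1825 on the ketogenic diet and 705 on both when both diets were fitted together. The order turned to 1837 on chow and 986 on the ketogenic diet when each diet was fitted alone. Without the 3 arrays standing apart the counts were 1929 and 2244. The spread between arrays differed by diet in intestine. The median within-group SD was 0.108 on chow and 0.138 on the ketogenic diet, and 28.5% of genes had the larger SD on chow. Fitted together or alone, each diet has the same curves, and only the estimate of spread differs, shared by both diets or separate. The order thus turned with that estimate, and which diet had more rhythmic genes in intestine stays open. Genes rhythmic on both diets peaked later on the ketogenic diet by a median of 0.75 h. The difference between diets was called for 5 genes: Mgll, BC018473, Pxmp4 and Acacb had larger amplitudes on the ketogenic diet and Dhcr7, an enzyme of cholesterol synthesis, on chow (adjusted p = 0.0169 for each). Acacb went from an amplitude of 0.19 to 0.79 and Mgll from 0.14 to 0.60, with ketogenic peaks at ZT21.0 and ZT20.7. Acacb was not called with a pseudocount of 1 (adjusted p = 0.0640) or without chow ZT20 replicate 31 (0.0672). Without chow ZT8 replicate 12 or ketogenic ZT8 replicate 24 neither Acacb (0.0657 and 0.0644) nor Pxmp4 (0.0647 and 0.0637) was called. Dhcr7 was not called without chow ZT12 replicate 32 (0.0661) or without ketogenic ZT12 replicate 11 (0.0559) or replicate 31 (0.0527). The count was 3 without chow ZT8 replicate 12 or ketogenic ZT8 replicate 24, 20 without chow ZT20 replicate 30 and 41 without the 3 arrays standing apart. No list was over-represented among the 5 genes by Fisher's exact test (smallest unadjusted p = 0.0072, adjusted p = 0.133). Cholesterol synthesis had 20 of 24 genes rhythmic on chow and 2 on the ketogenic diet. Without the 3 arrays 12 of 24 were called for a difference (Fisher's exact test, adjusted p = 2.6e-23). These genes were correlated (estimated correlation 0.63), which the test does not take into account, so this p value can be too small.

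Between the tissues the diet effect differed for 3444 of 10872 genes, 1883 with the higher effect in liver and 1561 with the higher effect in intestine. Acacb fell 3.36-fold in liver and rose 4.71-fold in intestine, a log2 difference of -3.98 ± 0.12 (adjusted p = 1.8e-33). Me1 fell 1.92-fold in liver and rose 3.83-fold in intestine (-2.88 ± 0.13). Tff3, Elovl6 and Tm6sf2 fell in liver and were not called in intestine in the limma fit over both tissues. Their log2 differences in intestine were -0.12 for Tff3 (adjusted p = 0.420), 0.10 for Elovl6 (adjusted p = 0.209) and 0.00 for Tm6sf2 (adjusted p = 0.978). Ifit1 rose in liver and fell in intestine (2.80 ± 0.17), as did Irf7 (1.44 ± 0.08), Ddx60 (1.68 ± 0.11), Gpat3 (1.73 ± 0.11) and Ppm1k (1.21 ± 0.08). By list, all 12 interferon genes tested had the higher effect in liver (median 0.82, camera adjusted p = 6.3e-15; adjusted p = 0.0155 with an estimated correlation). In drug metabolism 13 of 16 had it (adjusted p = 3.5e-08; adjusted p = 0.0155 with an estimated correlation), and in lipogenesis 12 of 18 had the lower effect in liver and 2 the higher (median -0.80, adjusted p = 1.3e-12; adjusted p = 0.0155 with an estimated correlation). Of 2860 genes called in both tissues, 913 rose in both (407 would be expected of independent lists), 1341 fell in both (988 expected) and 606 moved in opposite directions. Across genes, which are not independent replicates, the effects had a Pearson r of 0.18 and a Spearman rho of 0.33.

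The effect of diet on rhythm differed between the tissues for 17 genes. The interferon-inducible genes Rnf213, Tor3a and Adar (adjusted p = 3.2e-03 for each), Trim30a (6.7e-03) and Rsad2 (7.7e-03) all had a larger amplitude on the ketogenic diet than on chow in liver. Rnf213 went from 0.06 to 0.70 in liver and from 0.26 to 0.15 in intestine. Camk1d went from 0.26 to 0.74 in liver and from 0.14 to 0.21 in intestine (adjusted p = 0.0138). The count was 11 without liver ketogenic ZT12 replicate 11 and 34 without the 3 intestine arrays standing apart, and 16 without the 2 liver chow arrays. Genes rhythmic in both tissues numbered 314 on chow (153 expected of independent lists) and 831 on the ketogenic diet (546 expected).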

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

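The tests of explanations and the counts over other splits in this part, the clock times and the list tests between tissues were chosen after the results were seen; the tests of single genes between tissues and of lists at an unadjusted p under 0.01 were planned.

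The effect of diet differed between liver and intestine in a direct test for 3444 genes, and its effect on rhythm for 17. Of the genes with the smallest adjusted p, the log2 difference of liver minus intestine effect was 1.253 for Acsf2, 1.44 for Irf7, 1.73 for Gpat3, 2.80 for Ifit1, 1.21 for Ppm1k and 1.68 for Ddx60. On the other side Acacb had -3.98, Me1 -2.88, Tm6sf2 -0.83, Tff3 -3.22 and Elovl6 -1.70. For rhythm the adjusted p of the tissue difference was 0.00318 for Rnf213, Adar and Tor3a, 0.00669 for Trim30a, 0.0077 for Rsad2 and 0.0138 for Camk1d. By list the median difference was -0.80 for lipogenesis, 0.53 for cholesterol synthesis (adjusted p = 2.1e-10; adjusted p = 0.487 with an estimated correlation), 0.42 for drug metabolism, 0.083 for the respiratory chain and TCA cycle (adjusted p = 3.1e-03; adjusted p = 0.686 with an estimated correlation), -0.31 for cell cycle (adjusted p = 2.1e-03; adjusted p = 0.487 with an estimated correlation) and 0.82 for interferon response. The shift of clock time differed between the tissues by -1.34 h.

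Interferon response genes rose in liver with a peak late in the dark phase. More leukocytes in the ketogenic livers would raise leukocyte markers, but the highest of 16 such markers had a log2 difference of 0.21, against a median of 0.64 for the interferon list. This is a mean over the day: 4 of 12 macrophage and Kupffer cell markers passed for a rhythm difference at an unadjusted p under 0.01, so a change of these cells with the time of day stays open. The rise was not that of a few livers, since 17 of 18 ketogenic arrays lay above the chow mean of their time point. If both tissues came from the same mice, which the labels do not state, a response throughout the body would be expected in intestine. The median of the 12 interferon genes tested there was -0.34. T and B lymphocyte markers (median -0.45) and MHC class II genes (-0.94) were lower there too, so fewer immune cells could have masked a rise. A response throughout the body is therefore not excluded. Also open is whether hepatocytes or resident cells respond to the diet itself, which may be called a hypothesis, and whether an infection or another exposure of the ketogenic mice differed by time of day; no test here separates these.

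More genes were rhythmic in liver on the ketogenic diet (4552 against 2190). The 2 chow arrays with clock times far from their labels, ZT8 replicate 12 and ZT12 replicate 17, read 12.5 h and 7.75 h from 1504 genes outside the clock lists on ketogenic curves, so an exchange of their time points is a candidate explanation for these arrays. It is not the whole cause of the difference: exchanged, they gave 2686 rhythmic genes on chow and 4620 on the ketogenic diet, a ratio of 1.72 in place of 2.08. The highest count of 135 exchanges alone is weak evidence, since in intestine exchanging ketogenic ZT0 replicate 1 and ZT16 replicate 22 raised the count from 1825 to 3612 although their clock times followed their labels. These counts do not test a smaller spread on the ketogenic diet, since both diets shared 1 estimate of spread in the fit. With each diet fitted alone 1729 genes were rhythmic on chow and 4348 on the ketogenic diet. The median ratio of within-group SD was 0.999, which argues against a smaller spread there. The median ratio of amplitudes was 1.23 over all tested genes and 1.11 over the 1580 genes rhythmic on both diets.

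Clock genes of the intestine were late on the ketogenic diet. Collection of the ketogenic mice earlier than labelled would shift the liver as well, if both tissues came from the same mice, which the labels do not state; the shifts differed by -1.34 ± 0.48 h. The 3 arrays standing apart do not carry it, since without them the shift was -1.30 h. With the balance of crypt and villus genes as a covariate it was -1.29 ± 0.25 h, which argues against that balance as the cause. A later phase of the intestinal clock under this diet, by changed meal times for example, may be the explanation, and feeding times were not measured here.

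For each result 100 splits of the arrays into groups of the same sizes were counted, the real one included. For the results listed next only the real one gave a count as large, 1 of 100. That is the smallest share that 100 splits can give, so chance is argued against but not excluded. In liver the counts were 6012 for the diet effect (highest other 8), 2190 and 4552 rhythmic genes (9 and 1205), 148 rhythm differences (3) and 2 rhythm lists (0). With at most 3 rhythm differences the other splits left few genes from which a list could be called, so the rhythm lists add little. In intestine the counts were 6345 (1729), 1113 and 1825 (3 and 759) and 5 (1), and between tissues 3444 (38). For the tissue difference in rhythm the splits were made with a fit to centred values, whose real count was 56 (1 of 100 splits, highest other 5); the 17 genes reported come from another fit, which was not run over the splits. The splits do not argue against chance for the number of lists called by camera. In liver 6 of 100 splits gave 11 or more (highest other 13), and in intestine 16 of 100 gave 12 or more (highest other 16). For rhythm lists in intestine 0 were called, which 100 of 100 splits must equal or exceed (highest other 1), so the splits say nothing about chance there. Why single other splits gave up to 1205 genes in liver and 1729 in intestine was not tested.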

How the results depend on the processing

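Runs with the 3 intestine arrays or the 2 liver chow arrays left out, or those 2 exchanged, were chosen after the results were seen; the others were planned. The counts of genes for diet in either tissue and between tissues stayed within 1.5 times under every alternative except a 1.5-fold minimum, which gave 237 in liver and 161 in intestine. The named genes' diet effects kept direction and call in 3276 of 3276 runs leaving out an array and 756 of 756 other runs. These genes were chosen from the same data for large or clear differences, so this says little about the other called genes. List calls were kept in 803 runs leaving out an array and 162 other runs, with 25 and 33 lost. Those lost when 1 array was left out were cholesterol synthesis, enteroendocrine markers and MHC class II in intestine and gluconeogenesis in liver. A 60th percentile filter lost those 4 and also tuft markers (adjusted p = 0.433) and gluconeogenesis in intestine (0.160), and no filter lost the respiratory chain and TCA cycle (0.0801) and amino acid catabolism (0.142) in liver. Camera with an estimated correlation called 0 lists in liver and 0 in intestine, and fry called 19 and 25, but not cell cycle in intestine (adjusted p = 0.0882). The liver rhythm difference (148) was 98 without a filter, 44 with the interaction test and 480 among rhythmic genes alone, and 86 to 451 leaving out 1 array: 86 without chow ZT4 replicate 6, 93 without ketogenic ZT12 replicate 30, 97 without ketogenic ZT12 replicate 11 or chow ZT16 replicate 7, 451 without ketogenic ZT4 replicate 20. The intestine rhythm difference (5) was 2 with a 60th percentile filter, 18 with quantile normalization, 15 with median centring, 11 with a trend, 63 among rhythmic genes alone and 41 without the 3 arrays, and 3 to 20 leaving out 1: 3 without chow ZT8 replicate 12 or ketogenic ZT8 replicate 24, 8 without chow ZT0 replicate 2 or ketogenic ZT20 replicate 29, 9 without ketogenic ZT0 replicate 17, 11 without chow ZT4 replicate 25, 14 without chow ZT0 replicate 23, 15 without ketogenic ZT0 replicate 1, 20 without chow ZT20 replicate 30. The tissue difference in rhythm (17) was 11 with a 60th percentile filter, 37 with quantile normalization and 34 without the 3 arrays, and 11 to 34 leaving out 1: 11 without liver ketogenic ZT12 replicate 11, 26 without intestine ketogenic ZT12 replicate 31, intestine chow ZT20 replicate 13 or liver chow ZT4 replicate 4, 27 without intestine chow ZT0 replicate 22, 31 without liver ketogenic ZT4 replicate 20, 32 without liver ketogenic ZT0 replicate 1 or liver chow ZT4 replicate 24, 34 without liver ketogenic ZT8 replicate 7. Rhythmic genes by a test of any time difference were 1253 in liver and 597 in intestine on chow; in intestine each diet fitted alone gave 1837 on chow and 986 on the ketogenic diet, and chow without the 3 arrays 1929. Rhythm lists in liver (2) were 7 at an unadjusted p under 0.01 and 2 to 5 leaving out 1 array (4 without chow ZT16 replicate 8 or ketogenic ZT4 replicate 20, 5 without chow ZT12 replicate 16). In intestine (0) they were 5 at that p, 1 with quantile normalization, 1 with median centring, 2 without the 3 arrays, and 0 to 1 leaving out 1 (1 without chow ZT0 replicate 23, ketogenic ZT0 replicate 1, chow ZT20 replicate 30, chow ZT4 replicate 25 or chow ZT8 replicate 11). The amplitude difference of Ehbp1 reversed to 0.0038 with quantile normalization and ranged from -0.034 to 0.015 leaving out 1 array, and that of Tmie from -0.017 to 0.041. The cause of these changes was not tested, apart from the numbers of genes or arrays in the fit. Where each diet was fitted alone, only the estimate of spread differed. The title number as a block gave 3433 for the tissue difference in diet effect and 18 for that in rhythm. Values per sample from the workbook were not run, since it holds group means, and a trend was not run for the lists. Signal over background limits the folds of genes low in 1 group, which the filter on the mean over arrays keeps: with a pseudocount of 1 the liver diet difference of Cyp2b9 was 5.48 (4.95 with 16) and the intestine diet difference of Cyp4a10 4.39 (3.62), both log2.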

Other observations

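The tests of list members at an unadjusted p under 0.01 were planned, and those without 3 intestine arrays were chosen after the results were seen. Fisher's exact test treats genes as independent, so its p values below can be too small for lists of correlated members.

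Cholesterol synthesis genes of the intestine had a daily rhythm on chow that few of them had on the ketogenic diet. At an unadjusted p under 0.01 for a difference in rhythm, 13 of 24 passed (Fisher's exact test, adjusted p = 1.1e-15), and Mvk and Cyp51 were chosen after their values were seen: Mvk went from an amplitude of 0.50 to 0.13 (adjusted p = 0.0612) and Cyp51 from 0.47 to 0.06 (adjusted p = 0.325), with chow peaks at ZT11.3 and ZT12.4. PPARA targets went the other way, with 11 of 31 called rhythmic on chow and 23 on the ketogenic diet, and 7 of 31 passed for a difference at that p (adjusted p = 1.9e-05). Ppargc1a, a coactivator of oxidative metabolism, had an amplitude of 0.12 on chow and 0.53 on the ketogenic diet (adjusted p = 0.0612). Core clock (5 of 16, adjusted p = 8.2e-05), clock output (4 of 13, 5.9e-04) and lipogenesis genes (3 of 18, 0.0283) were also over-represented at that p. By genes past the adjusted threshold, the lists called without the 3 arrays standing apart were cholesterol synthesis (12 of 24, adjusted p = 2.6e-23) and clock output (2 of 13, 0.0149), and PPARA targets were not called. In 2 of those arrays, ketogenic ZT0 replicate 1 and ZT8 replicate 26, the PPARA list lay 0.48 and 0.45 above the rest of its group (SD of the others 0.18).

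Genes of the unfolded protein response were rhythmic in liver for 7 of 20 on chow and 17 of 20 on the ketogenic diet, and heat shock genes for 8 of 16 and 12 of 16; neither list was over-represented among the rhythm differences (Fisher's exact test, adjusted p = 1). In the tables the authors deposited, JTK_CYCLE had a p under 0.05 for 5881 of 25006 probe sets in liver on the ketogenic diet, 3741 on chow and 2011 on both. In intestine it had 3009, 3600 and 1249, with more on chow. BIO_CYCLE had 5570, 3884 and 1603 in liver and 2776, 4331 and 798 in intestine. These counts use the deposited ADJP values of each tool, not the BHQ values deposited beside them. They count probe sets, so they cannot be compared directly with the gene counts above.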
